A study of Homo sapiens with 3 samples.

How the data were processed

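Paired-end TruSeq RNA libraries were made from 1.3 µg of total RNA of SK-N-BE(2) cells, per the labels' protocols. There were 3 libraries, 1 each of control cells and of cells given ATO at 2 µM or 4 µM for 12 h. The authors deposited FPKM values, fragments per kilobase of transcript and mapped library size, for each gene and library, per the file headers. The aligner, the counting tool and their versions are not given in the sources used here. The submitters' processing notes name the mouse builds GRCm38 and mm10, whereas the rows carry human gene symbols and human Ensembl identifiers. The descriptions of 25196 rows also name a human gene nomenclature source (HGNC), so the rows are those of a human annotation. Its build and release could not be settled from the values, so no coordinates are printed. Whether strand was used in counting is not given either, so overlapping and antisense genes are treated as uncertain.

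The table held 34520 rows, of which 1378 were at 0 in each library, 8952 were named by an Ensembl identifier only and 359 had a repeated name. Counts were not in the table used here, and the tests planned for counts were replaced by the planned treatment of FPKM as deposited. To learn the depth, low FPKM values of genes with a single transcript in GENCODE 29 were multiplied by the transcript length. The most frequent product was 0.0280 in the control, 0.0272 at 2 µM and 0.0282 at 4 µM, whose inverses are 35.7, 36.8 and 35.4 and scale with the number of counted units in each library. Within a tolerance of 0.01, 14.2%, 13.4% and 14.4% of the low values were whole multiples, so reads were not recovered. Whether the unit is a fragment or a mate is open. If 2 units make a fragment, a 2 kb transcript at 1 FPKM rests on about 36 fragments (35.7 in the control), a counting CV of about 16.7%. FPKM summed to 256459 in the control, 262632 at 2 µM and 246878 at 4 µM, and the 10 highest rows held 24.6%, 23.0% and 21.7% of these sums.

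Rows with a mean of at least 1 FPKM were considered, 12433 in all. They comprised 11105 with a symbol, 657 without, 54 read-through rows, 513 pseudogenes and 104 small RNAs. For each comparison the log2 ratio of FPKM + 1 was computed, and a row passed the size rule at an absolute value of at least 1. With 1 library per group there are no residual degrees of freedom between conditions. A straight line through the doses would leave 1, but it would measure departure from a line and not replicate spread, and it was not used. Each of 29 gene lists was described by its median and by the number of 10000 random lists of the same size, drawn from considered rows and matched on mean expression in 20 bins, with a median as low or as high. This describes these libraries and is no test between conditions. It was computed for every list, including 3 with 1 considered gene. The lists covered N-Myc and MYC targets, MYCN and its partners, N-Myc repressed genes, adrenergic and mesenchymal identity, neuronal differentiation, metallothioneins, NRF2 targets, heat shock, the integrated stress response, endoplasmic reticulum chaperones, p53 targets, the BCL2 family, immediate early genes, replication, mitosis, cholesterol synthesis, hypoxia and glycolysis, proteasome, autophagy, interferon, histones, ribosomal proteins, mitochondrial genes, oxidative phosphorylation and 4 lists of other cell types.

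The genes named were fixed by rule before the data were examined, as were the lists, the size rule and most other settings tried. MYCN, MYC, MAX, ODC1, HMOX1 and CDKN1A were always named. For 4 µM against control the 12 largest increases and 12 largest decreases with the same direction at 2 µM were named, for the other comparisons the 5 largest of each, and in each list up to 4 members with the largest absolute log2 fold at 4 µM. Rows without a symbol, read-through rows and pseudogenes were counted and not named. Some genes that this rule covers are not reported here. A few further genes were singled out after their values were seen, namely TERT, SLC1A5, WWTR1 and RET in the report and, in the closing section, COL1A2, POSTN, FAP and the members of gene families and read-through rows with their components.

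The overlap of doses was set beside 100 simulations of unchanged libraries with a shared control and an assumed noise SD of 0.204 on the log2 scale, set from the spread of the 2 µM folds as if all of it were noise and equal for all rows, and beside the overlap of independent lists. The procedure was tested on simulated data for 4 µM against control with 12447 genes and a noise SD of 0.1. It called 0 of 50 genes planted at 1.5-fold, below the size rule, and 0 of 12197 unchanged genes. It recovered 50 of 50 genes planted at log2 folds of 1.5, 50 of 50 at 2.0 and 50 of 50 at 3.0. That noise is below the 0.204 assumed above and far below the size rule, so false calls were all but impossible and their rate was not tested. Genes were planted only well above the expression filter, so recovery near 1 FPKM was not tested. For GC content and transcript length, the longest GENCODE 29 transcript of each gene was used, older symbols were matched through a table of gene names, and the median fold of genes in the same of 10 by 10 bins was subtracted. This covered 11363 considered rows (91.4%). Subtracting bin medians also removes the median of all rows, so a corrected median includes a centring. The longest transcript need not be the one expressed, so the length correction may be incomplete. The matching of symbols was incomplete, with 28 of 33 integrated stress response genes and 54 of 55 N-Myc and MYC targets matched. No considered histone gene could be matched, so that check is void for the histone list.

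The other settings fixed beforehand were pseudocounts of 0.1 and 5, no expression filter, a mean of at least 10 FPKM, median-of-ratios centring, upper-quartile scaling, a 1.5-fold rule and random lists not matched on expression. Rescaling to TPM, leaving out read-through, pseudogene, unnamed and small RNA rows, and the GC and length correction were added after seeing the data. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.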

Results

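RNA was sequenced from SK-N-BE(2) cells, an established human neuroblastoma line that carries amplified MYCN, after 12 h with arsenic trioxide (ATO) at 2 µM or 4 µM, and from control cells. The series names ATO as an inhibitor of the binding of N-Myc, the transcription factor encoded by MYCN, to DNA, so the comparisons ask which transcripts differed from control at each dose. Each group had 1 library, so no value below has a replicate check, and no p-value, SD or SE is given. The deposited values were FPKM for 34520 rows, of which 12433 had a mean of at least 1 FPKM over the 3 libraries and were considered. The numbers of rows at 1 FPKM or more were 12606 in the control, 12337 at 2 µM and 12149 at 4 µM. Depth inferred from the spacing of low values was alike, at 1.03 times the control for the 2 µM library and 0.991 times for the 4 µM library. Log2 folds are of FPKM + 1, which understates the difference of low genes, and a row passed the size rule at an absolute log2 fold of at least 1.

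At 4 µM, stress genes were higher and MYCN, adrenergic identity genes and N-Myc target genes were lower than in the control. HMOX1, which encodes the heme-degrading enzyme heme oxygenase 1, had 9.17 FPKM in the control and 1770 FPKM at 4 µM, a log2 fold of 7.44. MYCN went from 832 FPKM in the control to 412 FPKM at 2 µM and 197 FPKM at 4 µM, log2 folds of -1.01 and -2.07. The 55 considered targets that N-Myc and MYC activate had a median log2 fold of -0.60, and the 22 adrenergic identity genes a median of -1.23. In all, 521 rows were higher and 655 were lower by the size rule, 1176 of the 12433 considered.

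The largest increases that had the same direction at 2 µM were led by HMOX1. GDF15, a stress-induced cytokine of the TGF-beta superfamily, had 1.09 FPKM in the control and 94.5 FPKM at 4 µM (log2 fold 5.52). Metal-binding metallothioneins followed, with log2 folds of 5.41 for MT1G, 4.46 for MT2A, 3.69 for MT1E and 3.30 for MT1X. SLC7A11, the cystine transporter subunit, went from 7.61 to 93.7 FPKM (3.46) and FOSL1, an AP-1 subunit, from 6.69 to 78.0 FPKM (3.36). ADM2, a peptide hormone gene, had a log2 fold of 3.35, OSGIN1 of 3.24, the fatty acid binding protein gene FABP3 of 3.21, and SAT1, which encodes the polyamine-acetylating enzyme, of 3.16. CDKN1A, the gene of the cell cycle inhibitor p21, went from 4.93 to 46.6 FPKM (3.01). The MT1 genes are near-identical copies of each other, so their separate values are uncertain.

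Among the largest decreases, IGFBP5, which encodes a binding protein of insulin-like growth factors, went from 103 FPKM in the control to 8.19 FPKM at 4 µM (log2 fold -3.50). The gene of another such binding protein, IGFBP3, went from 151 to 19.0 FPKM (-2.92). LINGO4 had a log2 fold of -3.50, the R-spondin receptor gene LGR5 of -2.94, C11orf96 of -2.93, METTL7A of -2.90 and the adaptor gene DOK4 of -2.86. MMP11, a matrix metalloproteinase gene, had -2.70, ISLR -2.68, the phosphatase gene PTPRR -2.65 and the cholecystokinin receptor gene CCKAR -2.60.

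**Figure D1:**
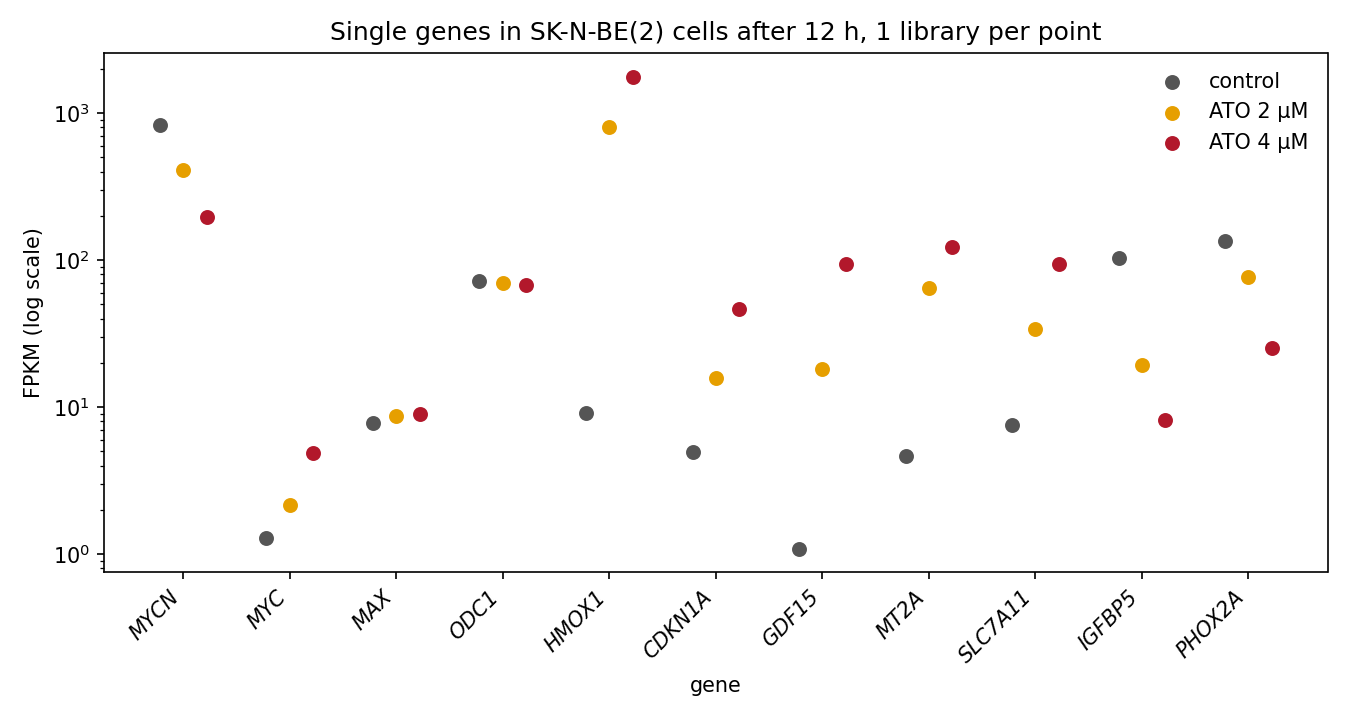
FPKM (log axis) of 11 genes in the control, ATO 2 µM and ATO 4 µM libraries, 1 point per library. MYCN ran from 832 to 412 to 197 FPKM and HMOX1 from 9.17 to 808 to 1770 FPKM, while MAX stayed between 7.84 and 8.97 FPKM.

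Of the 55 considered N-Myc and MYC activated targets, mostly genes of ribosome assembly and metabolism, 13 were lower and 1 was higher by the size rule at 4 µM, and 52 had a log2 fold below 0. None of 10000 random lists matched on expression had a median as low as -0.60. CAD, which starts pyrimidine synthesis, went from 28.9 to 7.74 FPKM (log2 fold -1.78), RRP9 had -1.44, BOP1 -1.41 and the importin gene IPO4 -1.36. SLC1A5, a glutamine transporter gene, was the member that was higher (1.09). ODC1, a classic MYC target for polyamine synthesis, had 71.9 FPKM in the control and 68.2 FPKM at 4 µM (-0.08), and its sign turned under either scaling between libraries. TERT, the remaining listed member, lay below the expression filter, at 1.06 and 0.192 FPKM.

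Within the list of MYCN and its partners, 2 of 16 genes were higher and 2 were lower. MYC itself was low but higher with dose, at 1.28, 2.15 and 4.84 FPKM (log2 fold 1.36 at 4 µM), and MXD1, a MAX partner that opposes MYC, went from 2.12 to 12.1 FPKM (2.07). MAX, the common dimer partner, had 7.84 and 8.97 FPKM. MYCNOS, the antisense gene of MYCN, had -1.66, but without a stated strand its reads cannot be separated from those of MYCN. The median of this list was -0.06 and turned to 0.10 with median-of-ratios and 0.11 with upper-quartile scaling. The genes listed as repressed by N-Myc went both ways, with 4 of 13 higher and 1 lower, a median of -0.34, which turned to 0.62 among genes with a mean of at least 10 FPKM, and a mean of 0.25. A correction for GC content and transcript length took the median of this repressed list to -0.18. Here CDKN1A and NDRG1, a stress-responsive gene with a log2 fold of 2.70, were higher, as was CLU (1.27).

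Adrenergic identity genes, which mark the sympathetic state of neuroblastoma cells, included 14 lower and 0 higher members of 22, and 0 of 10000 random lists had a median as low. HAND1 went from 106 to 18.6 FPKM (log2 fold -2.44), PHOX2A from 136 to 25.3 FPKM (-2.38) and the noradrenaline transporter gene SLC6A2 from 8.04 to 0.902 FPKM (-2.25). The mesenchymal identity list had 4 of 15 genes higher and 1 lower with a median of 0.12, which turned to -0.15 among genes with a mean of at least 10 FPKM, and 949 of 10000 random lists had a median as high. Its higher members were FOSL1, MAFF (1.71), FOSL2 (1.37) and WWTR1 (1.08), and TWIST1 was lower (-1.19). Among 21 neuronal differentiation genes 1 was higher and 4 were lower, namely SCG2 (-1.99), STMN2 (-1.32), ELAVL4 (-1.26) and GAP43 (-1.12). Their median of -0.02 turned to 0.13 with median-of-ratios and 0.15 with upper-quartile scaling. Fibroblast-associated genes were lower beside the adrenergic list, with 5 of 8 past the size rule and a median of -1.09, including LUM (59.2 to 11.2 FPKM), COL3A1 (20.5 to 5.45 FPKM) and DCN (5.89 to 1.14 FPKM).

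Stress lists were higher together at 4 µM. Each of the 7 considered metallothionein and zinc export genes passed the size rule (median log2 fold 3.30). MT1G, MT1E and MT1X had under 1 FPKM in the control, so they were considered through their values with ATO. MT1H, MT1L and MT3 lay below the filter, at 1.52, 0.0513 and 0 FPKM at 4 µM. Of the targets of NRF2, the regulator of the oxidative stress response, 20 of 29 were higher and 0 lower (median 1.73), with SRXN1 at 3.07 beside HMOX1, SLC7A11 and OSGIN1. Integrated stress response genes had 28 of 33 higher (median 1.60), including TRIB3, a pseudokinase gene that went from 3.61 to 39.6 FPKM (3.14). The heat shock list had 11 of 27 higher (median 0.97). HSPA1A (2.98) and HSPA1B (2.74) share reads as near-identical copies and are uncertain apart, while the small heat shock gene HSPB8 had 2.32 and the co-chaperone gene BAG3 2.22. No random list among 10000 had a median as high for any of these 4 lists.

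Endoplasmic reticulum chaperone genes did not move as a list, with 3 of 21 higher and 1 lower. Their median was -0.03 and their mean 0.02, and the median turned to 0.12 with median-of-ratios and 0.14 with upper-quartile scaling. DNAJB9 (1.25), HERPUD1 (1.23) and XBP1 (1.21) were higher and the disulfide isomerase gene PDIA4 was lower (-1.22). The proteasome list had 4 of 31 higher, with a median of 0.69 and 0 of 10000 random lists as high. PSMD2 (1.54), PSMD14 (1.19), PSMC1 (1.10) and PSMC4 (1.01) were the members past the size rule. Of 21 autophagy genes 4 were higher (median 0.29, 32 of 10000 random lists as high), namely the cargo receptor gene SQSTM1 (2.77), GABARAPL1 (2.34), MAP1LC3B (1.78) and ULK1 (1.06).

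Hypoxia and glycolysis genes were higher, 9 of 27 against 1 lower, with a median of 0.67 and 0 of 10000 random lists as high. Besides NDRG1, the glucose transporter gene SLC2A3 (1.55), ENO2 (1.40) and HK1 (1.38) led. The immediate early and AP-1 list had 5 of 21 higher (median 0.46, 1 of 10000 random lists as high), among them DUSP5 (2.27), GADD45A (1.35) and ATF3 (1.25). Of 22 p53 targets 4 were higher (median 0.25, 32 of 10000 random lists as high), which were GDF15, CDKN1A, PMAIP1 (1.77) and the death receptor gene TNFRSF10B (1.63). In the BCL2 family of 12 genes, which control apoptosis, PMAIP1 and MCL1 (1.07) were higher, and BMF (-2.06) and BCL2 (-1.12) were lower. The family's median was 0.23 and its mean 0.10, and after a correction for GC content and transcript length the median was 0.37 (193 of 10000 random lists as high), which took the list outside the central 95%.

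Cell cycle lists were lower at 4 µM by less than the size rule for most members. Of 33 replication genes 4 were lower, MCM7 (-1.49), PRIM1 (-1.16), MCM3 (-1.14) and E2F2 (-1.03), and the median was -0.58 (1 of 10000 random lists as low). Each of the 30 G2 and mitosis genes had a log2 fold below 0 and none passed the size rule (median -0.47, 0 of 10000 random lists as low), with TOP2A at -0.97, DLGAP5 at -0.86, KIF20A at -0.81 and AURKB at -0.77. Each of the 22 cholesterol synthesis genes was below 0 as well (median -0.48, 12 of 10000 random lists as low), and DHCR7 (-1.19), PMVK (-1.14) and MVK (-1.02) passed the rule. The highest members were at -0.05 for G2 and mitosis and -0.06 for cholesterol synthesis. The median of all considered rows was -0.13, against 0.01 with median-of-ratios and 0.03 with upper-quartile scaling. That each member was below 0 may therefore not hold after scaling. After the correction for GC content and transcript length the medians of the replication, G2 and mitosis, and cholesterol synthesis lists were -0.44, -0.33 and -0.34, each with at most 18 of 10000 random lists as low.

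The other lists lay within the central 95% of random lists at 4 µM, apart from the leukocyte list, which rested on 1 gene. Nuclear genes of oxidative phosphorylation had a median of -0.24 over 36 genes, with NDUFA8 at -0.83, NDUFB10 at -0.82, ATP5F1A at -0.73 and CYC1 at -0.73. The 13 genes of the mitochondrial genome, listed as a sign of RNA quality, had a median of -0.19, led by MT-ATP8 (-0.50), MT-ATP6 (-0.46), MT-CO3 (-0.36) and MT-ND2 (-0.35). For 52 cytosolic ribosomal protein genes the median was -0.17, with RPL7 at -0.48, RPL22 at -0.42, RPL14 at -0.41 and RPS25 at -0.37, and it turned to 0.02 with upper-quartile scaling. The 7 replication dependent histones had a median of 0.25 and the 7 considered interferon response genes 0.10, with IRF7 higher (1.03) and IFI44, ISG15 and IFI6 at 0.62, -0.30 and -0.18. H2BC5, H2BC12, H4C8 and H2BC21 had -0.72, 0.33, 0.31 and 0.27. After the correction for GC content and transcript length the mitochondrial genome median was 0.0007 and the ribosomal protein median -0.0004. The corrected medians were -0.13 for oxidative phosphorylation and 0.32 for the interferon list, and all 4 lists stayed inside the central 95%. Markers of other cell types had 1 considered gene in each of 3 lists, among them CD68 of leukocytes (0.534 to 4.87 FPKM, log2 fold 1.94) and EPCAM of epithelium (-0.04, positive under either scaling). The other 8 listed leukocyte genes lay below the filter, none above 0.230 FPKM in the control, 0.844 FPKM at 2 µM or 0.266 FPKM at 4 µM, and each was highest at 2 µM.

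**Figure D2:**
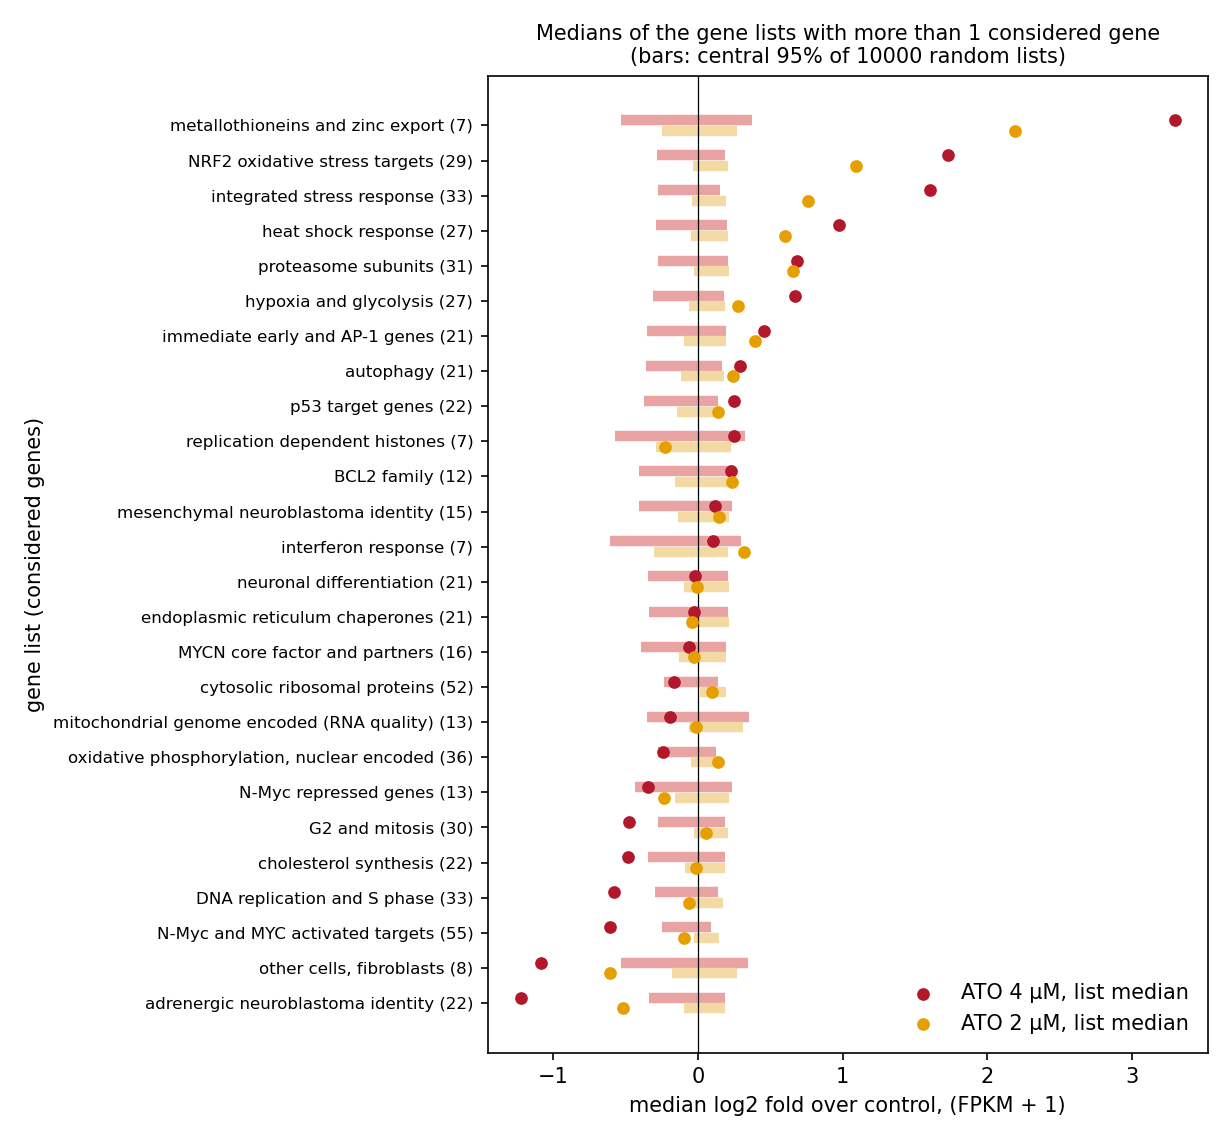
Median log2 fold over control of each gene list with more than 1 considered gene at 4 µM and 2 µM, with bars for the central 95% of 10000 random lists matched on expression. Metallothioneins lay highest at 3.30 and adrenergic genes lowest at -1.23 at 4 µM; the lists of MYCN and its partners, neuronal differentiation, endoplasmic reticulum chaperones and ribosomal proteins turned sign at 4 µM under another scaling.

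The count at 4 µM depended on the pseudocount, with 1949 rows past the size rule at 0.1 and 390 at 5. The median log2 fold of all considered rows was -0.13, and after median-of-ratios centring (median 0.01) 62.0% of the rows past the rule were higher, 64.0% after upper-quartile scaling, against 44.3% as deposited.

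At 2 µM the stress genes were already higher and MYCN was lower, while the N-Myc target list had moved little. The largest increases were HMOX1 (808 FPKM, log2 fold 6.31), MT1G (3.69), MT2A (3.54), GDF15 (3.19) and MT1E (2.86). Among the largest decreases were IGFBP5 (-2.36), CCKAR (-2.04) and the tyrosine kinase gene BLK (5.57 to 0.869 FPKM, -1.81). By the size rule 144 rows were higher and 112 were lower, 256 in all. Of these, 40 had no symbol, 11 were read-through rows, 19 pseudogenes and 8 small RNAs, and 178 remained without such rows.

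At this dose 5 of the 7 metallothionein and zinc export genes (median 2.19), 16 of 29 NRF2 targets (1.09), 10 of 33 integrated stress response genes (0.76) and 6 of 27 heat shock genes (0.60) were higher, none of these lists having a lower member by the rule. The proteasome median of 0.66 was close to its value at 4 µM, with PSMC1 (1.06) and PSMD14 (1.04) past the rule. CDKN1A had 15.8 FPKM against 4.93 FPKM in the control. The N-Myc and MYC targets had a median of -0.10 and 0 of 55 genes past the rule, although 5 of 10000 random lists had a median as low. With the correction for GC content and transcript length this median was -0.15, and 0 of 10000 random lists were as low. Adrenergic genes had a median of -0.52, with 3 of 22 genes lower by the rule, RET and SLC6A2 among them, and the fibroblast-associated genes -0.61 with 0 of 8 past it. The median of the N-Myc repressed list was -0.23 (41 of 10000 random lists as low) against a mean of 0.13, and it turned to 0.43 among genes with a mean of at least 10 FPKM. Medians of 0.40 for immediate early and AP-1 genes, 0.28 for hypoxia and glycolysis, 0.24 for autophagy, 0.32 for the interferon list and 0.23 for the BCL2 family also lay above the central 95% of random lists. After the correction for GC content and transcript length the BCL2 median was 0.15, with 595 of 10000 random lists as high, so that call was lost, and the p53 target median of 0.14 came to lie above the central 95% (123 of 10000 as high against 369). Replication genes had -0.06 (238 of 10000 random lists as low) and lay inside the central 95% of lists not matched on expression, while G2 and mitosis genes had 0.06. With the correction these medians were -0.13 (22 of 10000 as low) and 0.0009.

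Of the 29 lists, 5 lay below and 11 above the central 95% of random lists at 2 µM, and 6 below and 10 above at 4 µM. If genes varied independently, 1.45 per comparison would by chance. Members of a list may vary together between single cultures, and some lists share members, such as SLC7A11 and GDF15, so these counts do not exclude chance. The leukocyte list of 1 gene is among those above at both doses. With a pseudocount of 0.1 the count of rows past the rule at 2 µM was 506, with 5 it was 61 and as TPM 919, and the share of higher rows was 51.2%, 72.1% and 39.9% in these settings against 56.2%.

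The question of dose was addressed by setting 4 µM against 2 µM. GDF15 (2.32), FLNC, an actin-binding filamin gene (18.6 to 83.8 FPKM, 2.12), FABP3 (2.07), BOLA2 (2.06) and SESN2, a stress-induced sestrin gene (8.60 to 38.7 FPKM, 2.05), had the largest increases. LINGO4 (-2.09), IGFBP3 (-1.89), the meiotic recombination gene MND1 (4.55 to 0.500 FPKM, -1.89) and the apelin receptor gene APLNR (63.8 to 18.4 FPKM, -1.74) were among the 5 largest decreases, with UPK3BL2, which had 4.09 FPKM at 2 µM and was listed at 0 at 4 µM. BOLA2 and UPK3BL2 have near-identical copies and are uncertain. By the size rule 142 rows were higher and 166 were lower at 4 µM than at 2 µM, 308 in all.

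The N-Myc and MYC targets differed between the doses by a median of -0.55, with 51 of 55 below 0, and MYCN by -1.06. Adrenergic genes (-0.70), G2 and mitosis genes (-0.50), replication genes (-0.45), cholesterol synthesis genes (-0.45), nuclear genes of oxidative phosphorylation (-0.42) and fibroblast-associated genes (-0.64) were lower at 4 µM as lists, each with at most 11 of 10000 random lists as low. Each of the 36 oxidative phosphorylation genes and of the 52 ribosomal protein genes (median -0.27, 167 of 10000 random lists as low) was below 0 as deposited. Their highest members were at -0.08 and -0.04. Between the doses the median of all considered rows was -0.12, against -0.01 with median-of-ratios and 0.01 with upper-quartile scaling. Counts of genes below 0 may therefore not hold after scaling. The correction for GC content and transcript length ended the ribosomal call (median -0.03, 720 of 10000 random lists as low). It took the medians to -0.39 for the N-Myc and MYC targets, -0.48 for adrenergic, -0.31 for G2 and mitosis, -0.29 for replication, -0.28 for cholesterol synthesis, -0.20 for oxidative phosphorylation and -0.57 for fibroblast-associated genes, each with at most 8 of 10000 random lists as low. The higher lists were the metallothioneins (0.92), integrated stress response (0.87), NRF2 targets (0.55), hypoxia and glycolysis (0.32), heat shock (0.30), AP-1 genes (0.26), endoplasmic reticulum chaperones (0.16) and autophagy (0.13). Their corrected medians were larger, at 1.19, 1.05, 0.74, 0.47, 0.40, 0.35, 0.27 and 0.28 in this order. Part of that rise is the removal of the median of all rows. The proteasome list had a median of -0.01, which turned to 0.12 with median-of-ratios and 0.14 with upper-quartile scaling, and to 0.20 after the GC and length correction, where it lay above the central 95% of random lists (142 of 10000 as high).

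Of the 1176 rows past the size rule at 4 µM, 211 (17.9%) had passed it in the same direction at 2 µM, 124 higher and 87 lower, and 5 had passed it in the opposite direction. Unchanged libraries simulated against a shared control, with an assumed noise SD of 0.204 for all rows, shared 0.09 rows on average. Noise of that size is far below the size rule, so a very small overlap was fixed in advance. Rows with more noise were not simulated, so the gap to 211 is no measure of agreement. Independent lists of these sizes, which leave the shared control out of account, would share 6.03 higher and 5.90 lower rows. The 2 µM value lay between control and 4 µM for 1136 of the 1176 rows (96.6%), but the same held for 97.0% of rows past the rule in the simulated unchanged libraries, so this share does not show a graded response. Across genes, which are not independent replicates, the folds at both doses had a Pearson r of 0.769 and a Spearman rho of 0.713, and 74.0% had the same sign. The simulated unchanged libraries gave an r of 0.50 and 66.6% of genes with the same sign, values that follow from giving each library equal noise.

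**Figure D3:**
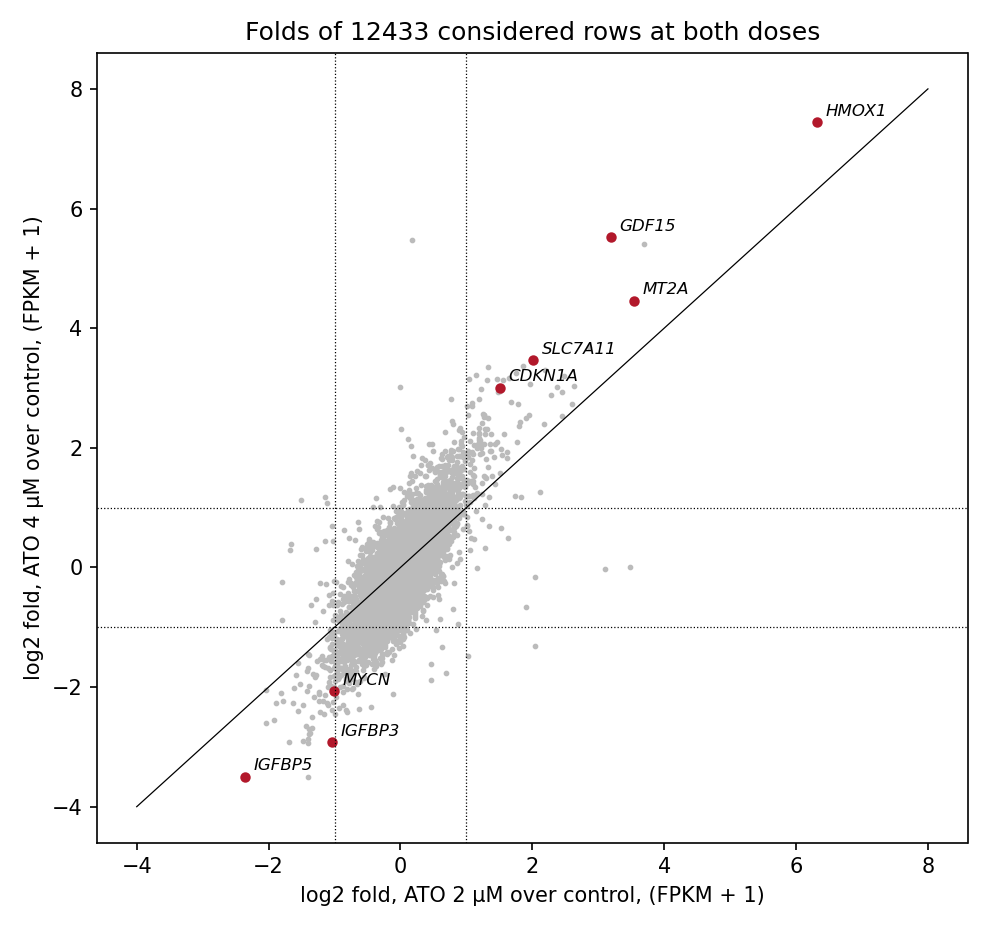
Log2 fold over control of FPKM + 1 at 2 µM (horizontal axis) and 4 µM (vertical axis) for the 12433 considered rows, with dotted lines at the size rule, a solid line of equal folds and named genes in red. HMOX1 lies at 6.31 and 7.44 and IGFBP5 at -2.36 and -3.50.

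The single control library could not be split, so part of the agreement between doses may come from it. After median-of-ratios centring 67.7% of the rows past the rule between the doses were higher at 4 µM, and 71.9% after upper-quartile scaling, against 46.1% as deposited.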

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

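Rescaling to TPM, leaving out special rows and the GC and length correction were chosen after seeing the data. The counts of rows past the size rule were 256 at 2 µM, 1176 at 4 µM and 308 between the doses. They were 506, 1949 and 735 with a pseudocount of 0.1, 61, 390 and 77 with 5, 103, 474 and 134 with a mean of at least 10 FPKM, 1120, 3470 and 1797 with a 1.5-fold rule, and 919, 2586 and 1069 as TPM. A larger pseudocount, a stricter filter and a looser rule move these counts by construction. TPM with the same pseudocount acts as a smaller one and considers 17056 rows. Without a filter, after either scaling between libraries and without read-through, pseudogene, unnamed and small RNA rows, each count stayed within 1.5 times. Without those kinds of row the counts were 178, 1020 and 233. The share of 4 µM rows already past the rule at 2 µM was 17.9%, and 21.3%, 14.1%, 20.9%, 27.1% and 23.5% with those same 5 settings in order, for which the cause was not tested. The N-Myc and MYC target median at 4 µM of -0.60 was -0.43 after upper-quartile scaling and -0.43 after the GC and length correction, and below 0 in each setting. Both of these settings also shift all genes, and median-of-ratios centring alone gave -0.45. The median of the N-Myc repressed list at 2 µM reversed from -0.23 to 0.43 with a mean of at least 10 FPKM, where fewer of its genes remain. No named gene past the size rule at 4 µM changed sign in any setting. The call of a list against random lists depended on matching for replication and oxidative phosphorylation genes at 2 µM. Not run were the filter on counting intervals and another deposited unit, which need values not used here. No paired analysis was possible because each group had 1 library, and no library could be left out.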

Other observations

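The GC and length correction was chosen after the list medians were seen, and its expected outcomes were written before its results for 4 lists, those weighed below, and not for the other lists or for families. Gene families sharing a symbol root, some of which share members with the fixed lists, were described in the same way. At 4 µM 32 of 131 lay outside the central 95% of random lists, where 6.55 would by chance if genes varied independently. Mitochondrial ribosomal protein genes (MRPL) had a median log2 fold of 0.15 at 2 µM and -0.31 at 4 µM over 51 genes, 47 of them below 0, with MRPL24 at -1.59 and MRPL12 at -1.18. The 29 MRPS genes of the same ribosome had 0.11 and -0.32, inside the central 95% of random lists (374 of 10000 as low at 4 µM). The 10 coenzyme Q genes (COQ) had a median of -0.65 at 4 µM, although COQ10B was higher at 1.40. Secreted ADAMTS proteases had -0.56 at 2 µM and -0.75 at 4 µM over 11 genes, with ADAMTS19 at -1.72, and semaphorins (SEMA) -0.32 and -0.52 over 14 genes. RAB genes of vesicle traffic had a median of 0.26 over 56 symbols, with RAB7A going from 31.6 to 67.8 FPKM. None of these family medians changed sign under either scaling. After the GC and length correction MRPL genes had 0.07 at 2 µM, with 1199 of 10000 random lists as high, so the higher median at 2 µM was lost, and -0.16 at 4 µM (146 of 10000 as low), while MRPS genes had -0.12 at 4 µM (1219 of 10000 as low). At 4 µM the corrected medians of COQ, ADAMTS, SEMA and RAB genes were -0.42, -0.45, -0.40 and 0.39, each still outside the central 95% of random lists.

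The fibroblast-associated genes, fixed as a list of other cells, had log2 folds from -2.30 to -0.28 at 4 µM, a range of 2.02. COL1A2, POSTN and FAP of this list were below the filter, at 0.391, 0.174 and 0.0487 FPKM in the control, while LUM had 59.2 FPKM. Whether the line itself expresses the considered members was not tested, and this pattern was not weighed further.

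N-Myc and MYC targets and adrenergic genes were lower at 4 µM as lists. The median of all considered rows was -0.13, and after median-of-ratios centring that of the N-Myc targets was -0.45. After removal of the GC content and transcript length trend the N-Myc target median was -0.43 and that of the adrenergic genes -1.13, with 0 of 10000 random lists as low for either. This argues against a trend with GC content and length of the longest annotated transcripts as the whole cause. Lengths of the expressed transcripts were not known. An effect of ATO, the difference the design names, stays open as untested, as do differences between single cultures. MYCN transcript itself was lower at both doses, so these libraries do not separate reduced binding of N-Myc from reduced MYCN.

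Short transcripts differed between the doses. Transcript length correlated with the fold across genes at a Spearman rho of -0.25 at 2 µM, 0.09 at 4 µM and 0.32 for 4 µM against 2 µM. For ribosomal proteins the correction for GC content and transcript length took the difference between doses from a median of -0.27 to -0.03, with 720 of 10000 random lists as low. Part of that move is the removal of the median of all rows, which was -0.12 between the doses. A length trend between libraries may account for the rest of that difference. For nuclear oxidative phosphorylation genes the same correction took -0.42 to -0.20 with 8 of 10000 random lists as low. It used the longest annotated transcript of each gene, which need not be the one expressed. An incomplete correction could leave such a remainder, so whether the trend is the whole cause stays open there. Whether the trend arose in library preparation, in RNA quality or in the cells was not tested.

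Read-through rows, which join neighbouring genes, differed more than other rows. At 4 µM 25.9% of them passed the size rule against 9.19% of rows with an ordinary symbol, and at 2 µM 20.4% against 1.60%. The row RPL36A-HNRNPH2 had 0.344 FPKM in the control and 59.1 FPKM at 4 µM, while HNRNPH2 had 61.8 and 61.4 FPKM. If reads were being assigned now to the joint row and now to a component, the component would move in the opposite direction, which it did in 73.7% of 19 rows (14), short of the 75% set beforehand. These rows were pooled over the 3 comparisons. How often a component would move opposite without shared reads was not computed. A move of any size counted, HNRNPH2's included. The sum with the component took the median absolute log2 fold from 1.74 to 0.32, and that of RPL36A-HNRNPH2 to 0.94, but adding a more abundant gene shrinks a fold whether or not reads were shared. Shared reads and a real difference cannot be told apart by these values.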
